A study of Mus musculus with 24 samples.

How the data were processed

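RNA-seq of 24 libraries of CJ9 mouse embryonic stem cells was analysed: wild-type and Setd3 knock-out cells at days 0, 2, 3 and 4 of an endoderm differentiation, 3 in each of 8 groups. Per the labels' protocols, stem cells were kept with LIF on inactivated mouse embryonic fibroblasts, separated from these, grown in differentiation medium for 2 days and then passaged as single cells into medium with Activin A; RNA was isolated with an RNeasy Plus kit and polyadenylated RNA was made into libraries. Groups and replicate numbers were taken from the sample labels.

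The authors deposited a table of whole-number read counts per gene and library, not normalised, with Ensembl gene identifiers and gene names. Per the submitters' processing notes, Trimmomatic and HISAT2 were used with the genome build GRCm38.p6; their versions, the counting tool, the annotation, the use of strand and the treatment of reads that map to several places are not given in the sources used here. Counts of antisense and overlapping genes, such as Evx1os and Evx1, and of families of close copies, such as Zscan4 and Xlr3, are therefore uncertain. The table had 55401 entries, of which 55141 identifiers were found in GENCODE M21, which gave coordinates on GRCm38, and 29207 had counts. All 37 mitochondrially encoded entries were 0 in every library, so the list of mitochondrially encoded genes could not be tested. A floor of 3 counts over a group was used for a group with 0 counts, and 95% intervals of counts for groups with 1 to 3 counts. Without molecular identifiers, floors and intervals cover counting error only.

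CPM used library sizes scaled by TMM. Differences were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test (glmQLFit and glmQLFTest, robust) with 1 model over all 24 libraries and 8 groups, after its filter on low counts by group, which left 17144 genes (common biological coefficient of variation 0.0906). There were 10 comparisons: knock-out against wild-type at each of 4 days, 3 successive steps of the wild-type, and the knock-out effect at days 2, 3 and 4 minus that at day 0. Adjusted p-values are Benjamini-Hochberg values over the tested genes of a comparison, with 0.05 as threshold.

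Before the data were examined, 30 gene lists were fixed: naive pluripotency, general pluripotency, formative and primed epiblast, primitive streak and mesendoderm, definitive endoderm, canonical Wnt targets, Wnt ligands and receptors, intracellular Wnt components, secreted Wnt inhibitors, Nodal and Activin targets, BMP targets, FGF and ERK feedback, mesoderm, neuroectoderm, extraembryonic endoderm, trophoblast, fibroblast feeder, two-cell-like, actins and SRF targets, p53 targets, proliferation, glycolysis and hypoxia, epithelial, mesenchymal, imprinted, Hox and Y-linked genes, chromosomal neighbours of Setd3, mitochondrially encoded genes, and methyltransferases of the SETD3 class with actin regulators. The 29 lists with at least 4 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists, and again with an estimated correlation. Members were also adjusted over the list alone. Over the 10 comparisons, 2 to 7 lists had a median, a mean and a test that differed in sign, none of them past the test.

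Named genes followed a rule fixed in advance: Setd3 always; at each day the 5 highest and 5 lowest log2 fold changes between genotypes among genes past the threshold, with no overlap between the libraries of both groups (which chance gives for 10% of genes at 3 against 3), a higher group mean of at least 10 CPM and a gene symbol that is not a clone or model name; for each wild-type step 3 and 3; for day 4 minus day 0, 4 and 4. Any list member could be named as an example, and examples are the members with the lowest adjusted p. Named outside this rule, chosen after their values were seen, were Sox17 at day 4, Axin2 at day 2, T in the wild-type step to day 3, and the genes given for cilia and for a delay apart from Xlr3a and Nxf3 (2 with clone or model names). Some genes that it takes are not reported here.

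Alternatives planned before the data were examined were DESeq2's size factors, no filter on low counts, only the groups compared, the replicate number as a block, each library left out in turn, DESeq2's Wald test (1.42.0) for genes and the estimated correlation for lists. Leaving out chromosome 8 and chromosome 12 from 90 Mb, and taking day 2 in place of day 0 as the reference of the genotype effect, were added after the data were seen. Chromosome 12 segments were set on genes with a mean of at least 5 CPM and at least 10 genes per segment, and corrected for GC content and length by a loess fit (span 0.5). The test was tried on simulated counts for knock-out against wild-type at day 0 with 16951 tested genes: it recovered 53.7% of 67 genes changed 1.5-fold, 85.1% of 67 changed 2-fold and 97% of 66 changed 4-fold, with 11 calls among 16751 unchanged genes.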

Results

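Mouse embryonic stem cells of the CJ9 line, either wild-type or carrying a CRISPR-Cas9 knock-out of Setd3, were followed through a serum-free differentiation towards endoderm. Setd3 encodes a SET-domain protein known as a histidine methyltransferase of actin, and the study asked whether it acts on endoderm differentiation through canonical Wnt signalling. Activin A, a ligand of the Nodal and Activin pathway, was added from day 2. Polyadenylated RNA was sequenced at days 0, 2, 3 and 4, with 3 libraries for each genotype and day, giving 24 libraries in 8 groups. Gene counts summed to between 18531390 and 24244958 per library, 20020 to 22665 genes had at least 1 count, and the 10 most abundant genes took 4.17% to 5.07% of a library's counts. Expression levels are CPM, counts scaled to a common library total, as mean ± SD of n = 3 libraries. After log2 fold changes, ± is their size over the square root of the test's F, not a fitted standard error. Gene values without a unit are log2 fold changes. The knock-out is 1 line, and the labels do not say that the replicates were separate cultures. The p-values therefore measure the spread between these samples only, which may be technical.

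Cells were kept on mouse embryonic fibroblasts with LIF before differentiation, and fibroblast transcripts were measurable at day 0. The 18 genes of the feeder list summed to 1257, 2260.0 and 1915 CPM in the wild-type libraries of day 0 and to 3286, 2334 and 1236 CPM in those of the knock-out, and to means of 136 and 183 CPM at day 2.

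**Figure D1:**
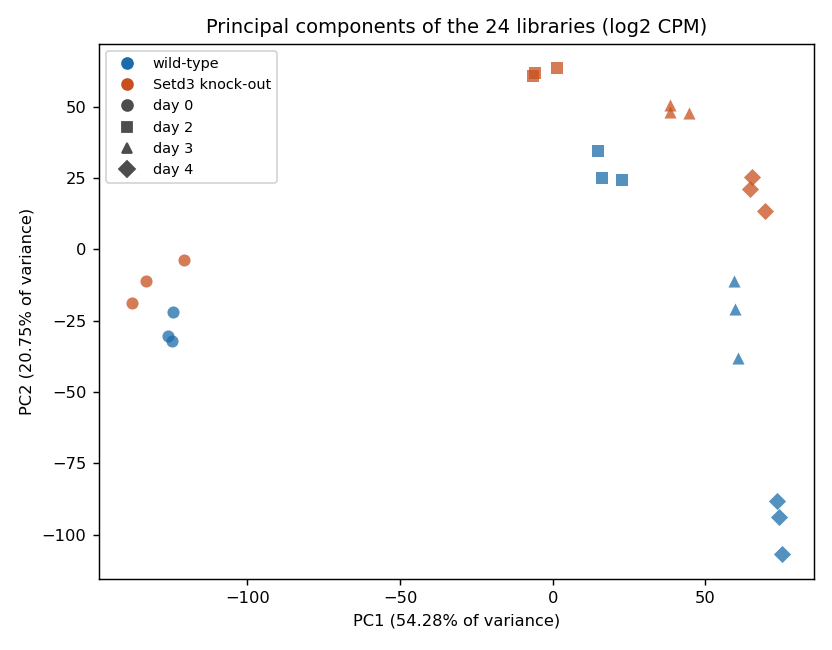
Principal components of the 24 libraries, computed on log2 CPM, with component 1 (54.28% of the variance) on the horizontal axis and component 2 (20.75%) on the vertical axis; each point is a library, coloured by genotype and shaped by day. Day 0 groups lie close and the knock-out is spread.

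Setd3 transcripts were reduced but present in every knock-out library. The gene (ENSMUSG00000056770, GRCm38 chromosome 12, 108106431 to 108179314, minus strand) was at 122 ± 4.49 CPM in the wild-type and 46.3 ± 3.49 CPM in the knock-out at day 0, at 97.5 ± 0.62 CPM against 30.9 ± 2.62 CPM at day 2, at 120.2 ± 4.42 CPM against 31.6 ± 2.15 CPM at day 3, and at 124 ± 3.71 CPM against 29.9 ± 1.01 CPM at day 4. The log2 fold changes were -1.40 ± 0.06, adjusted p = 1.84e-14, -1.66 ± 0.06, adjusted p = 8.06e-16, -1.93 ± 0.06, adjusted p = 2.85e-17 and -2.05 ± 0.06, adjusted p = 6.21e-18, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which gives every gene-wise adjusted p below. The 3 knock-out libraries lay below the 3 wild-type libraries at each day. The remaining level was 38% of the wild-type at day 0, 31.7% at day 2, 26.3% at day 3 and 24.2% at day 4. Which exon was edited is not given in the sources used here, so these counts do not show whether a protein was made.

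Genes around Setd3 were lower in the knock-out as well. Of the 9 tested genes of the list of chromosomal neighbours, 5 fell at day 0, 8 at day 2, 8 at day 3 and 7 at day 4, where 1 rose; adjusted over the list alone, 5, 8, 9 and 7 fell and 1 rose at day 4. Yy1, a zinc finger transcription factor, had log2 fold changes of -0.82 ± 0.04, -1.01 ± 0.05, -0.87 ± 0.04 and -0.68 ± 0.04. Ccdc85c changed by -0.74 ± 0.07, adjusted p = 8.45e-08 at day 0 and -0.87 ± 0.07, adjusted p = 2.52e-09 at day 2. Eml1, a microtubule-associated protein, changed by -1.82 ± 0.19, adjusted p = 4.14e-08 at day 3 and -3.01 ± 0.19, adjusted p = 2.52e-12 at day 4. The list passed the camera test at every day (adjusted p = 7.87e-10 at day 0, adjusted p = 4.43e-12 at day 2, adjusted p = 3.14e-07 at day 3 and adjusted p = 0.00057 and adjusted p = 0.0828 with an estimated correlation at day 4).

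Along chromosome 12 the change followed position. From Cep128 (start 90998492) to Vrk1 (end 106077426), 50 genes with at least 5 CPM on average had median log2 fold changes of 1.16, 1.28, 1.17 and 1.27 at days 0, 2, 3 and 4, and 43 of them were on the higher side at all 4 days. From Bcl11b (start 107910403) to the last gene measured (end 119262855), 61 genes apart from Setd3 had medians of -0.73, -0.89, -0.86 and -0.86, and 57 of them were on the lower side at all 4 days. Chromosome 8 was slightly higher along its length, with medians of 0.27, 0.26, 0.23 and 0.25 over 574 genes, against medians between -0.09 and 0.10 on the other autosomes and X. The 5 genes of the Y chromosome had medians between 0.08 and 0.24. Both blocks began at the same genes when set from day 0, 2 or 3 alone; from day 4 alone they began at Ptpn21 and Setd3. These segments were found after the data were seen. Of the genes named below, Cdh1, Dusp4, Klf2, Mcm5, Sfrp1, Triml1, Triml2, Vat1l and Zfp42 lie on chromosome 8, Gsc, Itpk1, Rps6ka5, Serpina3h, Tcl1 and Ttc7b in the raised block, and Rian, like Ccdc85c, Eml1 and Yy1, in the lowered block.

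**Figure D2:**
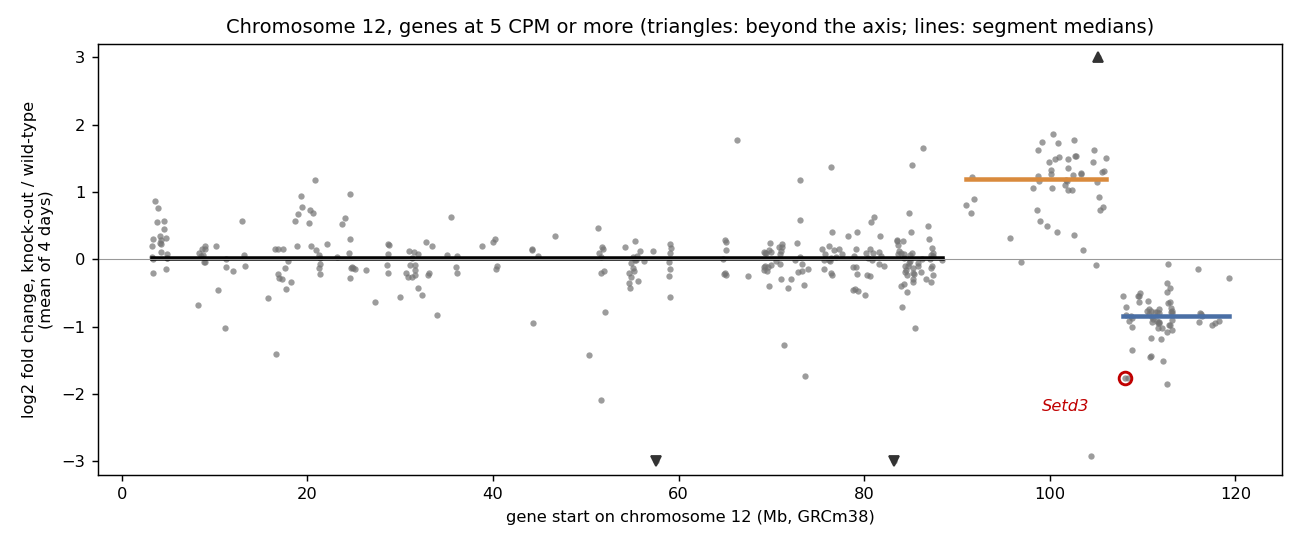
Log2 fold change of knock-out against wild-type, averaged over the 4 days, for genes of chromosome 12 with at least 5 CPM (vertical axis) against gene start in Mb (horizontal axis); points are genes, triangles are genes beyond the plotted range, horizontal lines are segment medians and Setd3 is circled. The segment of 50 genes lies around 1.20 and the distal segment of 61 genes around -0.83.

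In the wild-type, naive pluripotency genes fell and formative genes rose over the first 2 days. All 16 naive genes fell, among them the transcription factors Klf4, from 212 ± 22.3 to 2.4 ± 0.284 CPM (log2 fold change -6.46 ± 0.13, adjusted p = 1.73e-21), Nanog, from 444 ± 7.15 to 39.8 ± 2.71 CPM (-3.48 ± 0.10), and Klf5 (-3.65 ± 0.13). All 12 genes of the formative and primed epiblast rose, including the growth factor Fgf5, from 21.5 ± 3.11 to 138 ± 10.3 CPM (2.68 ± 0.08, adjusted p = 2.6e-18), and the zinc finger genes Zic5 (1.93 ± 0.07) and Zic2 (2.42 ± 0.08). The counts were unchanged when adjusted over each list alone, and both lists passed the camera test (naive adjusted p = 5.79e-36, formative adjusted p = 3.91e-27). Of the 8 Nodal and Activin targets 6 fell and none rose (adjusted p = 1.58e-07 and adjusted p = 0.0561 with an estimated correlation). Examples were the inhibitory Smad gene Smad7 (-4.13 ± 0.15) and the Nodal co-receptor Tdgf1, from 616 ± 66 to 36.4 ± 5.19 CPM. All 10 two-cell-like genes fell (adjusted p = 1.58e-07 and adjusted p = 0.0842 with an estimated correlation). Zscan4d was at -6.73 ± 0.36 and Zscan4c, a near-identical copy, at -5.90 ± 0.40.

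Genes of stromal cells fell over the same interval. All 18 feeder genes fell (adjusted p = 7.02e-07 and adjusted p = 0.385 with an estimated correlation). Examples were the lysyl oxidase gene Lox, from 278 ± 59.3 to 0.75 ± 0.229 CPM, and the microfibril gene Mfap5 (-4.01 ± 0.38). With them fell all 18 tested Hox genes (adjusted p = 0.000216 and adjusted p = 0.385 with an estimated correlation). Hoxb9 was 1 of them (-4.88 ± 0.40). Of 9 mesenchymal genes 6 fell (adjusted p = 0.00424 and adjusted p = 0.588 with an estimated correlation). Examples were the repressor Zeb1 (-4.14 ± 0.25) and the filament gene Vim, from 808 ± 98.4 to 81 ± 10.4 CPM. Of 18 extraembryonic endoderm genes 11 fell and 1 rose (adjusted p = 0.0173 and adjusted p = 0.54 with an estimated correlation), the laminin gene Lamc1 being lower (-1.29 ± 0.09). The epithelial list moved the other way, with 10 of 12 genes higher (adjusted p = 1.58e-07 and adjusted p = 0.0842 with an estimated correlation). Examples were the junction genes Ocln (2.35 ± 0.11) and Cdh1, from 527 ± 29.7 to 1147 ± 24.9 CPM. In glycolysis and hypoxia 10 of 17 genes fell and 2 rose (adjusted p = 0.0173 and adjusted p = 0.716 with an estimated correlation). Vegfa was at -2.52 ± 0.12 and Hk2 at -1.18 ± 0.09. Among single genes the strongest rises were of Slc35d3, a nucleotide sugar transporter family member (6.72 ± 0.33, adjusted p = 1.62e-12), Sez6 (6.13 ± 0.24, adjusted p = 1.54e-16) and Skida1 (5.41 ± 0.16, adjusted p = 1.12e-18). Besides Lox (-8.54 ± 0.44, adjusted p = 2.02e-11), the strongest falls were of Serpina3h (-8.18 ± 0.52, adjusted p = 3.16e-11) and S100a4, which went from 10.8 ± 1.75 CPM to 2 counts over the 3 libraries of day 2. In this step 10936 of 17144 tested genes changed, 5485 higher and 5451 lower, 2155 and 2618 of them at least 2-fold. Counts adjusted over the list alone were the same for these lists. Of the 29 tested lists, 10 passed, 2 of them with an estimated correlation.

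Between day 2 and day 3, the first day after Activin A was added, genes of the primitive streak and of Nodal signalling rose together. All 12 tested genes of primitive streak and mesendoderm rose (adjusted p = 2.19e-22). Examples were the ligands Wnt3, from 2.66 ± 0.966 to 84.1 ± 11.1 CPM (4.98 ± 0.20, adjusted p = 3.17e-14), and Nodal (3.63 ± 0.16), and the T-box transcription factors Eomes, from 15.9 ± 4.66 to 486 ± 70.5 CPM (4.93 ± 0.24, adjusted p = 5.87e-11), and T (Brachyury), from 30.9 ± 12.5 to 222 ± 73.7 CPM (2.84 ± 0.37, adjusted p = 9.25e-06). Of the 8 Nodal and Activin targets 7 rose (adjusted p = 1.48e-28). Smad7 was 1 of them (3.49 ± 0.15), as was Nodal. Canonical Wnt targets were higher for 10 of 15 genes and lower for 3 (adjusted p = 0.00226 and adjusted p = 0.248 with an estimated correlation; 11 higher and 3 lower adjusted over the list alone). The negative feedback gene Axin2 was at 2.52 ± 0.18, and the transcription factor Sp5 went from 2.67 ± 1.79 to 65 ± 28 CPM. Among 28 Wnt ligands and receptors 11 rose and 4 fell (adjusted p = 0.000231 and adjusted p = 0.248 with an estimated correlation). Examples were the receptor Fzd10 (4.04 ± 0.16) and the ligand Wnt11 (5.69 ± 0.33). In definitive endoderm 9 of 15 genes rose and none fell (adjusted p = 0.00139 and adjusted p = 0.388 with an estimated correlation). Examples were the forkhead gene Foxa2, from 7.3 ± 3.38 to 149 ± 29.8 CPM, and the hormone precursor gene Trh (2.06 ± 0.11).

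Pluripotency genes fell in the same step, with exceptions. Of 16 naive genes 10 fell and 1 rose (adjusted p = 6.22e-05 and adjusted p = 0.248 with an estimated correlation; 1 higher and 11 lower adjusted over the list alone); Klf2 fell (-3.04 ± 0.22) and Nanog rose, from 39.8 ± 2.71 to 379 ± 17.3 CPM. In general pluripotency 6 of 10 fell and 2 rose (adjusted p = 0.00115 and adjusted p = 0.248 with an estimated correlation). Dppa4 was at -3.32 ± 0.18 and Tdgf1, also a Nodal target, at 4.18 ± 0.20. Epithelial genes fell for 7 of 12 (adjusted p = 0.00897 and adjusted p = 0.388 with an estimated correlation). Examples were the claudin genes Cldn3 (-1.65 ± 0.22) and Cldn4 (-1.95 ± 0.24). Of 19 genes of actins and SRF targets 9 rose (adjusted p = 0.00952 and adjusted p = 0.696 with an estimated correlation), the cytoplasmic actin gene Actg1 among them (0.57 ± 0.05). Imprinted genes fell for 10 of 17 and rose for 2 (adjusted p = 0.00952 and adjusted p = 0.248 with an estimated correlation; 3 higher and 10 lower adjusted over the list alone), a list call lost without chromosome 8 and distal 12 (adjusted p = 0.284), Rian being lower (-0.85 ± 0.08). Extraembryonic endoderm genes fell for 8 of 18 and rose for 2 (adjusted p = 0.0105 and adjusted p = 0.388 with an estimated correlation; 2 higher and 9 lower adjusted over the list alone), Apoe being lower (-1.67 ± 0.12). Feeder genes fell for 8 of 18 (adjusted p = 0.0266 and adjusted p = 0.714 with an estimated correlation), Thy1 among them (-1.78 ± 0.25). Among the strongest rises were those of the homeobox gene Evx1 (6.25 ± 0.38, adjusted p = 6.49e-11) and its antisense transcript Evx1os (6.08 ± 0.33), which cannot be told apart from Evx1 where counting ignores strand. The strongest falls were of Dnmt3l, a cofactor of DNA methylation (-4.09 ± 0.26, adjusted p = 5.75e-10), the transcription factor Ebf1 (-4.05 ± 0.21, adjusted p = 1.4e-13) and the protease Mmp3 (-3.66 ± 0.68, adjusted p = 0.000329). In all 7275 genes changed, 3665 higher and 3610 lower, 665 and 1703 of them at least 2-fold, and 12 lists passed, 2 with an estimated correlation. Counts not given separately were the same adjusted over the list alone.

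From day 3 to day 4 genes of definitive endoderm and of several other lineages rose. Of 15 definitive endoderm genes 14 rose and none fell (adjusted p = 1.69e-16). Examples were Shisa2 (3.29 ± 0.17, adjusted p = 6.06e-12) and the secreted Wnt antagonist gene Sfrp5, from 0.687 ± 0.304 to 68.1 ± 29.5 CPM (6.61 ± 0.37, adjusted p = 2.1e-11). BMP targets rose for 7 of 8 genes (adjusted p = 2.32e-05 and adjusted p = 0.0878 with an estimated correlation). Msx2 was at 5.62 ± 0.36 and Smad6 at 2.00 ± 0.16. Mesoderm genes did so for 9 of 13 with 1 lower (adjusted p = 0.0036 and adjusted p = 0.158 with an estimated correlation). The cardiac factor Tbx20 was at 5.31 ± 0.35 and the VEGF receptor gene Kdr at 5.15 ± 0.38. Extraembryonic endoderm genes did so for 11 of 18 (adjusted p = 1.67e-05 and adjusted p = 0.127 with an estimated correlation; 11 higher and 1 lower adjusted over the list alone). Examples were the nuclear receptor Hnf4a, from 0.0778 ± 0.0986 to 39.4 ± 15.6 CPM (8.84 ± 0.53, adjusted p = 1.69e-10), and Apoe (1.55 ± 0.12). Trophoblast genes did so for 4 of 6 (adjusted p = 0.00243 and adjusted p = 0.0878 with an estimated correlation). Ascl2 was 1 of them (5.41 ± 0.38). Imprinted genes rose for 13 of 17 and fell for 2 (adjusted p = 4.53e-07). Peg3 went from 429.7 ± 51 to 1500 ± 53.3 CPM, with Usp29 at 2.01 ± 0.13 and Mest at 1.45 ± 0.11. Glycolysis and hypoxia genes rose for 9 of 17 (adjusted p = 0.000137 and adjusted p = 0.461 with an estimated correlation). Examples were Vegfa (2.33 ± 0.11) and the glucose transporter Slc2a3, from 171 ± 5.35 to 2152 ± 359 CPM. Epithelial genes rose for 8 of 12 with 1 lower (adjusted p = 0.00206 and adjusted p = 0.341 with an estimated correlation). Examples were Ocln (1.02 ± 0.10) and the keratin Krt8 (2.60 ± 0.25).

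Pluripotency and cell cycle genes fell between these days. General pluripotency genes were lower for 8 of 10, with Sall4 higher (adjusted p = 9.86e-07 and adjusted p = 0.0878 with an estimated correlation; Dppa2 -3.36 ± 0.26, Sall4 0.80 ± 0.07). Naive genes were lower for 8 of 16 and higher for 3 (adjusted p = 0.0149 and adjusted p = 0.521 with an estimated correlation; Nanog -1.77 ± 0.09, Tbx3 5.70 ± 0.29). Formative genes were lower for 8 of 12 and higher for 2 (adjusted p = 0.0421 and adjusted p = 0.521 with an estimated correlation; Zic5 -0.79 ± 0.06, Lin28b -0.62 ± 0.06). Of 21 proliferation genes 16 fell and none rose (adjusted p = 7.13e-07 and adjusted p = 0.158 with an estimated correlation). Examples were the cyclin Ccne1 (-1.07 ± 0.06) and the replication factor Mcm5 (-0.63 ± 0.05). Of 19 genes of actins and SRF targets 12 fell and 1 rose (adjusted p = 0.00922 and adjusted p = 0.692 with an estimated correlation). Examples were Srf (-0.73 ± 0.07) and Myl9 (-2.45 ± 0.28). Feeder genes fell for 5 of 18 (adjusted p = 0.0421 and adjusted p = 0.7 with an estimated correlation), Thy1 among them (-2.43 ± 0.35). Besides Hnf4a, the strongest rises were of Akr1c19 (7.69 ± 0.52, adjusted p = 4.85e-10) and Pilrb1, which went from 3 counts over the 3 libraries of day 3 to 10.4 ± 1.64 CPM. By the naming rule the strongest falls were of Vat1l, on chromosome 8 (-3.76 ± 0.28, adjusted p = 1.1e-09), Fst (-3.28 ± 0.35, adjusted p = 7.79e-07) and Sall3 (-3.13 ± 0.27, adjusted p = 8.08e-09). In all 7803 genes changed, 3843 higher and 3960 lower, 1402 and 934 of them at least 2-fold, and 14 lists passed, 2 with an estimated correlation. Other list counts were the same adjusted over the list alone.

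**Figure D3:**
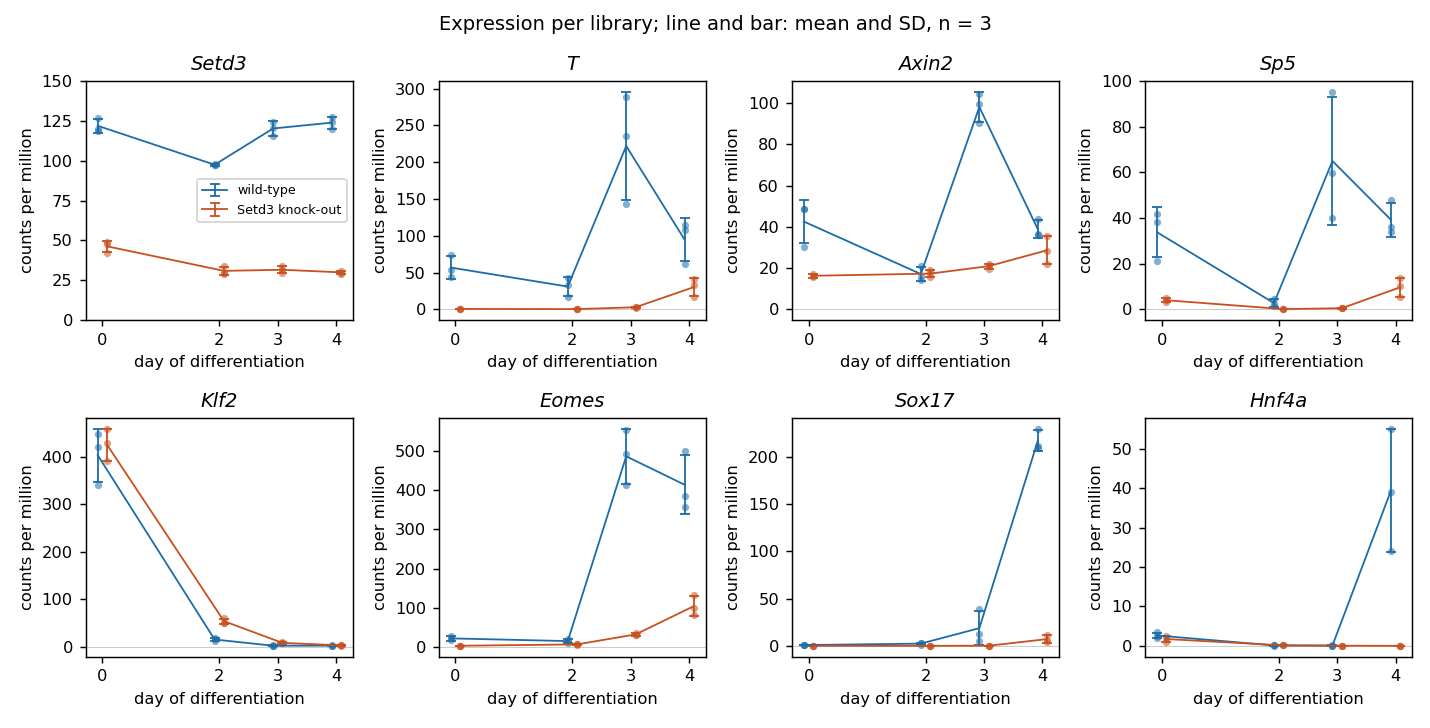
Expression in CPM (vertical axes, each with its own scale) against day of differentiation (horizontal axes) for Setd3, T, Axin2, Sp5, Klf2, Eomes, Sox17 and Hnf4a; points are libraries, lines join group means and bars are SD of n = 3, wild-type in blue and knock-out in orange. Eomes reached 486 ± 70.5 CPM in the wild-type at day 3 and 32.9 ± 2.81 CPM in the knock-out.

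At day 0, before differentiation, the knock-out lacked most of the primitive streak transcripts present in the wild-type cultures. T fell from 56.7 ± 15.4 to 0.427 ± 0.22 CPM (log2 fold change -7.06 ± 0.64, adjusted p = 7.06e-07), the ligand Fgf8 from 14.1 ± 4.21 to 0.307 ± 0.0374 CPM (-5.50 ± 0.48, adjusted p = 2.9e-07), and the ligand Wnt3 from 13.4 ± 2.95 to 0.808 ± 0.115 CPM (-4.04 ± 0.25, adjusted p = 1.07e-10). The LIM homeobox gene Lhx1 went from 18.3 ± 6.95 CPM to 3 counts over the 3 knock-out libraries, a ratio of 372-fold with a 95% counting interval of 131 to 1864. Cyp26a1, which encodes a retinoic acid hydroxylase, went from 10.8 ± 3.68 CPM to 2 counts, 358-fold with an interval of 93.3 to 2797. Of the 12 genes of primitive streak and mesendoderm 8 fell, none rose and 4 did not pass (0 higher and 10 lower adjusted over the list alone; adjusted p = 4.6e-19). Eomes was at -2.47 ± 0.29.

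Canonical Wnt targets fell with the streak genes. Of 15 genes 6 fell and none rose (0 higher and 7 lower adjusted over the list alone; adjusted p = 0.000294 and adjusted p = 0.153 with an estimated correlation). Examples were Axin2, from 42.5 ± 10.6 to 16.2 ± 0.895 CPM (-1.39 ± 0.18, adjusted p = 1.32e-05), the homeobox gene Cdx1 (-1.97 ± 0.30) and Sp5 (-3.11 ± 0.43). Of 28 Wnt ligands and receptors 9 fell and 2 rose (3 higher and 9 lower adjusted over the list alone; adjusted p = 0.00285 and adjusted p = 0.313 with an estimated correlation). Wnt8a was at -5.05 ± 0.51, Fzd10 at -1.14 ± 0.14 and, in the other direction, the co-receptor Lrp6 at 0.37 ± 0.05. Of 20 intracellular components 5 rose and none fell (adjusted p = 0.0428 and adjusted p = 0.625 with an estimated correlation). Examples were the destruction complex gene Apc (0.44 ± 0.06) and the co-repressor Tle4 (0.34 ± 0.07). All 10 two-cell-like genes fell (adjusted p = 7.91e-26). Zscan4d was at -3.82 ± 0.27, Zscan4a at -3.87 ± 0.31 and Zscan4c at -3.29 ± 0.30. Formative and primed genes fell for 4 of 12 (0 higher and 5 lower adjusted over the list alone; adjusted p = 1.61e-08). Examples were Fgf5, from 21.5 ± 3.11 to 1.25 ± 0.229 CPM, Dnmt3b (-0.82 ± 0.11) and Sox3 (-1.87 ± 0.29). Definitive endoderm genes fell for 5 of 15, with Trh higher (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.00301 and adjusted p = 0.451 with an estimated correlation): Foxa2 was at -3.22 ± 0.63, Tmprss2 at -3.83 ± 0.77 and Trh at 0.91 ± 0.10.

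Imprinted genes fell for 8 of 17 and rose for 1 (3 higher and 9 lower adjusted over the list alone; adjusted p = 0.000104 and adjusted p = 0.0521 with an estimated correlation). Examples were Peg3, from 162 ± 27.9 to 60.7 ± 1.55 CPM, its neighbour Usp29 (-2.05 ± 0.19), and Rian (-0.56 ± 0.08). In the lowered block of chromosome 12 lie 4 of the 17, Rian included, of which 3 were lower at days 0 and 2, 2 at day 3 and all 4 at day 4. Proliferation genes rose for 6 of 21 (7 higher and 0 lower adjusted over the list alone; adjusted p = 0.00198 and adjusted p = 0.451 with an estimated correlation), by 0.33 for the kinase Plk1 and 0.46 for Mki67. Lists that did not pass also held changed genes. In the epithelial list (adjusted p = 0.0775; 2 higher and 5 lower adjusted over the list alone) the keratins Krt8, from 62 ± 28.9 to 7.16 ± 0.218 CPM, and Krt18 (-2.35 ± 0.31) fell while Cdh1 rose (0.49 ± 0.06). The trophoblast factor Cdx2 fell (-5.03 ± 0.59), and the Y-linked gene Zfy1 rose (2.25 ± 0.30). None of the 18 feeder genes differed in the edgeR test (1 at unadjusted p under 0.05, 0 by DESeq2), and the same held for 18 Hox genes (1 and 0) and 9 mesenchymal genes (2 and 1). By the naming rule the strongest rises were of Tcl1, a co-activator of AKT (1.87 ± 0.14, adjusted p = 2.51e-08), the Y-linked Uba1y (1.73 ± 0.19, adjusted p = 3.04e-07), Itpk1 (1.71 ± 0.08, adjusted p = 1.89e-14), Ttc7b (1.70 ± 0.09, adjusted p = 4.01e-13) and Rps6ka5 (1.68 ± 0.10, adjusted p = 3.24e-12), all but Uba1y in the raised block. Xlr3a, a member of an X-linked family of close copies, was among the strongest falls (-6.17 ± 0.27, adjusted p = 3.78e-14).

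In this comparison 3611 of 17144 genes differed, 1810 higher and 1801 lower in the knock-out, and of the 690 that differed at least 2-fold 601 were lower. Of 29 lists 10 passed, 2 higher and 8 lower, and 4 passed with an estimated correlation. With the 6 libraries of day 0 alone in the fit, 1587 passed (1539 shared).

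At day 2 naive pluripotency genes were higher in the knock-out while streak genes were lower. Of 16 naive genes 14 were higher and none lower (adjusted p = 2.83e-18). Examples were Klf2, from 14.8 ± 3.04 to 53.6 ± 5.49 CPM (1.86 ± 0.15, adjusted p = 3.72e-08), the nuclear receptor Esrrb, from 12.3 ± 4.67 to 66 ± 11.7 CPM (2.43 ± 0.22, adjusted p = 2.58e-07), Klf5 (1.25 ± 0.13) and Tcl1 (3.39 ± 0.28). Of 10 general pluripotency genes 5 were higher and 1 lower (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.0323 and adjusted p = 0.48 with an estimated correlation). Dppa4 was at 0.86 ± 0.15 and Fgf4 at 0.98 ± 0.18. The streak list had 8 of 12 genes lower (0 higher and 9 lower adjusted over the list alone; adjusted p = 9.26e-09 and adjusted p = 0.174 with an estimated correlation): T went from 30.9 ± 12.5 to 0.201 ± 0.15 CPM (-7.22 ± 0.77, adjusted p = 2.48e-06) and Lhx1 from 12.7 ± 3.48 to 0.235 ± 0.145 CPM (-5.72 ± 1.11, adjusted p = 0.000821). Wnt3 was at -3.94 ± 0.45 and Fgf8 at -3.67 ± 0.60. Definitive endoderm genes were lower for 7 of 15 and higher for 2 (2 higher and 10 lower adjusted over the list alone; adjusted p = 0.00508 and adjusted p = 0.48 with an estimated correlation). Foxa2 was at -4.74 ± 0.60. Trh (1.00 ± 0.11) and the repressor Prdm1 (1.24 ± 0.27) were higher.

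Among canonical Wnt targets 5 of 15 were lower and 2 higher at day 2, and the list did not pass (adjusted p = 0.102). The receptors Tnfrsf19 (-1.60 ± 0.22) and Lgr5 (-2.40 ± 0.50) were lower, and Axin2 was at 17.1 ± 3.39 CPM in the wild-type and 17.3 ± 1.71 CPM in the knock-out (0.01 ± 0.19, adjusted p = 0.968), a difference whose sign changed with single libraries left out. Wnt ligands and receptors were lower for 11 of 28 and higher for 2 (2 higher and 13 lower adjusted over the list alone; adjusted p = 0.00268 and adjusted p = 0.342 with an estimated correlation). Fzd10 was at -1.71 ± 0.24. Genes of actins and SRF targets were lower for 5 of 19 (adjusted p = 0.0323 and adjusted p = 0.713 with an estimated correlation). The smooth muscle actin gene Acta2 was at -2.27 ± 0.47 and Ccn1 at -1.64 ± 0.38. Proliferation genes were higher for 12 of 21 (14 higher and 0 lower adjusted over the list alone; adjusted p = 0.00377 and adjusted p = 0.48 with an estimated correlation) by small amounts, such as 0.26 for Plk1 and 0.21 for the replication helicase gene Mcm2. Imprinted genes were lower for 7 of 17 and higher for 5 (5 higher and 10 lower adjusted over the list alone; adjusted p = 0.0139 and adjusted p = 0.342 with an estimated correlation), a call lost without chromosome 8 and distal 12 (adjusted p = 0.256). Peg3 was at -1.49 ± 0.09 and Usp29 at -1.91 ± 0.16. Y-linked genes were higher for 2 of 5 (adjusted p = 0.0495 and adjusted p = 0.342 with an estimated correlation), a call lost with DESeq2's size factors (adjusted p = 0.0503). In lists that did not pass, the microtubule protein gene Map2 (-0.99 ± 0.13) and the BMP target Id1 (-2.37 ± 0.38) were lower. The edgeR test called none of the 13 mesoderm genes (3 at unadjusted p under 0.05, 2 by DESeq2) and none of the 18 Hox genes (3 and 1).

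By the naming rule the strongest rises at day 2, besides Esrrb, were of Uba1y (3.48 ± 0.22, adjusted p = 1.65e-11), AU018091 (2.20 ± 0.19, adjusted p = 6.73e-08), Triml2 (2.10 ± 0.23, adjusted p = 2.29e-06) and Triml1 (2.05 ± 0.23, adjusted p = 2.22e-06), the last 2 on chromosome 8. Besides T and Lhx1 the strongest falls by this rule were of the X-linked genes Xlr3a (-6.13 ± 0.27, adjusted p = 3.76e-14), the RNA export gene Nxf3 (-3.80 ± 0.25, adjusted p = 3.67e-11) and Dgkk (-3.22 ± 0.53, adjusted p = 0.000196). In all 5480 genes differed, 2783 higher and 2697 lower, and of the 1255 that differed at least 2-fold 923 were lower. Of 29 lists 10 passed, 4 higher and 6 lower, 2 of them with an estimated correlation. Of the genes called at day 0, 1102 were higher on both days and 864 lower on both, where independent calls would give 294 and 283, and 94 were called in opposite directions.

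At day 3, a day after Activin A was added, most streak genes were lower in the knock-out than in the wild-type. Of 12 streak genes 11 were lower (adjusted p = 2.87e-15): Mixl1 was at 179.6 ± 76.5 CPM in the wild-type and 1.85 ± 0.574 CPM in the knock-out (-6.60 ± 0.40, adjusted p = 1.07e-09), Eomes at 486 ± 70.5 CPM and 32.9 ± 2.81 CPM (-3.88 ± 0.23, adjusted p = 5.94e-10), and T at 222 ± 73.7 CPM and 2.75 ± 0.776 CPM (-6.33 ± 0.48, adjusted p = 1.76e-08). Evx1 was at -5.61 ± 0.34 and Wnt3 at -2.37 ± 0.16. Definitive endoderm genes were lower for 10 of 15 and higher for 1 (1 higher and 11 lower adjusted over the list alone; adjusted p = 1.31e-05 and adjusted p = 0.236 with an estimated correlation). Examples were the secreted antagonist gene Cer1, from 93.6 ± 78.8 CPM to 5 counts over the 3 knock-out libraries (-10.21 ± 1.23, adjusted p = 2.33e-05), Foxa2, from 149 ± 29.8 to 5.55 ± 0.869 CPM (-4.74 ± 0.29, adjusted p = 1.07e-09), Foxa1 (-5.29 ± 0.56) and the transcription factor Gata6 (-7.41 ± 0.93, adjusted p = 7.16e-06). Cer1 and Gata6 varied widely among the wild-type libraries, Gata6 being at 23.5 ± 20.6 CPM. Mesoderm genes were lower for 6 of 13 and higher for 1 (1 higher and 8 lower adjusted over the list alone; adjusted p = 0.00832 and adjusted p = 0.236 with an estimated correlation). Snai1 was at -3.98 ± 0.28, Pdgfra at -5.22 ± 0.63 and Tal1, higher, at 2.01 ± 0.32.

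Canonical Wnt targets were lower for 9 of 15 and higher for 1 (1 higher and 10 lower adjusted over the list alone; adjusted p = 5.97e-06 and adjusted p = 0.0852 with an estimated correlation). Sp5 was at 65 ± 28 CPM in the wild-type and 0.411 ± 0.176 CPM in the knock-out (-7.28 ± 0.58, adjusted p = 3.12e-08), Axin2 at 98.2 ± 7.32 CPM and 20.9 ± 1.2 CPM (-2.23 ± 0.17, adjusted p = 6.19e-09), and Tnfrsf19 at -3.28 ± 0.22. Wnt ligands and receptors were lower for 13 of 28 and higher for 5 (adjusted p = 0.000171 and adjusted p = 0.18 with an estimated correlation). Wnt11 was at -4.17 ± 0.28, Fzd10 at -2.39 ± 0.14 and Fzd7, higher, at 0.84 ± 0.05. Nodal and Activin targets went both ways, 4 lower and 3 higher of 8 (adjusted p = 0.488): Gsc (-4.89 ± 0.40) and Tdgf1 (-1.33 ± 0.17) were lower and Smad7 (0.93 ± 0.12) higher.

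General pluripotency, naive and epithelial genes were higher at day 3. General pluripotency genes were higher for 6 of 10 and lower for 1 (adjusted p = 6.19e-05 and adjusted p = 0.177 with an estimated correlation). Examples were Fgf4, from 14 ± 4.66 to 110.1 ± 13 CPM (2.97 ± 0.20, adjusted p = 2.81e-09), Dppa4 (2.71 ± 0.18), Dppa2 (1.82 ± 0.16) and Utf1 (2.10 ± 0.19). Naive genes were higher for 10 of 16 and lower for 1 (11 higher and 2 lower adjusted over the list alone; adjusted p = 0.000652 and adjusted p = 0.311 with an estimated correlation), a call lost without chromosome 8 and distal 12 (adjusted p = 0.0563). Klf2 was at 2.10 ± 0.24, and Nanog lower, at 379 ± 17.3 CPM in the wild-type and 198 ± 2.87 CPM in the knock-out. The formative list did not pass (adjusted p = 0.061; 6 higher and 3 lower adjusted over the list alone), with 6 of 12 higher and 2 lower, the higher including Sall2 (1.33 ± 0.14) and Pou3f1 (2.02 ± 0.21). Epithelial genes were higher for 11 of 12 (adjusted p = 9.11e-07 and adjusted p = 0.118 with an estimated correlation). Examples were Cdh1 (0.62 ± 0.06) and the transcription factor Grhl2 (1.12 ± 0.11). Mesenchymal genes were lower for 5 of 9 (adjusted p = 0.0186 and adjusted p = 0.613 with an estimated correlation). Examples were the cadherin Cdh2 (-2.45 ± 0.29) and the repressor Zeb2 (-1.89 ± 0.24). The imprinted list did not pass (adjusted p = 0.104; 4 higher and 7 lower adjusted over the list alone), and Peg3 was at -1.79 ± 0.09. The edgeR test called none of 10 two-cell-like genes (0 at unadjusted p under 0.05, 0 by DESeq2) and none of 18 Hox genes (2 and 0).

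Besides Fgf4, the strongest rises at day 3 were of the sterol transporter Abcg1 (2.89 ± 0.21, adjusted p = 1.34e-09), the kinase Ttbk1 (2.88 ± 0.20, adjusted p = 5.48e-11), Slc35d3 (2.83 ± 0.21, adjusted p = 5.47e-09) and Dnmt3l (2.78 ± 0.28, adjusted p = 2.7e-07). Besides Cer1, Gata6 and Sp5 the strongest falls were of Lhx1, from 192 ± 134 to 0.399 ± 0.166 CPM (-8.90 ± 0.77, adjusted p = 1.03e-07), and Cyp26a1 (-8.37 ± 0.94, adjusted p = 1.97e-06). In all 7069 genes differed, 3563 higher and 3506 lower, 899 and 1124 of them at least 2-fold. Of 29 lists 10 passed, 3 higher and 7 lower, 2 of them with an estimated correlation.

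At day 4 all 15 definitive endoderm genes were lower in the knock-out (adjusted p = 5.66e-13). Sox17, an endoderm transcription factor, was at 217 ± 11.2 CPM in the wild-type and 7.22 ± 3.81 CPM in the knock-out (-4.91 ± 0.52, adjusted p = 3.65e-07), and Gata4 at 122 ± 35.4 CPM and 0.896 ± 0.0824 CPM (-7.08 ± 0.32, adjusted p = 1.16e-12). Shisa2 was at -3.29 ± 0.17 and Sfrp5 at -7.66 ± 0.40. Extraembryonic endoderm genes were lower for 15 of 18 (0 higher and 16 lower adjusted over the list alone; adjusted p = 6.23e-05 and adjusted p = 0.114 with an estimated correlation). Examples were Hnf4a, at 39.4 ± 15.6 CPM in the wild-type and 0 counts in the knock-out, at least 836-fold lower against a floor of 3 counts over the group, and the receptor gene Pth1r (-3.45 ± 0.32). Mesoderm genes were lower for 11 of 13 and higher for 1 (adjusted p = 0.000171 and adjusted p = 0.103 with an estimated correlation): Hand1 (13.4 ± 5.49 CPM in the wild-type) and Mesp1 (13.1 ± 1.76 CPM) had 0 counts in the knock-out, at least 285-fold and 277-fold lower, and Kdr was at -9.15 ± 0.56, adjusted p = 4.04e-11, Tbx20 at -5.60 ± 0.36 and Snai1 at -3.03 ± 0.25. BMP targets were lower for 7 of 8 (adjusted p = 9.15e-05 and adjusted p = 0.114 with an estimated correlation). Examples were Id1, from 110.3 ± 10.8 to 4.35 ± 1.83 CPM, Msx2 (-6.22 ± 0.38) and Smad6 (-2.58 ± 0.16). Trophoblast genes were lower for 5 of 6 and higher for 1 (adjusted p = 0.0135 and adjusted p = 0.114 with an estimated correlation). Ascl2 was at -3.66 ± 0.31 and Krt7 at -2.93 ± 0.27. Streak genes were lower for 11 of 12 (adjusted p = 0.00029 and adjusted p = 0.232 with an estimated correlation). Eomes was at 105 ± 25.4 CPM against 413 ± 74.8 CPM in the wild-type (-1.98 ± 0.21, adjusted p = 2.91e-07), Lhx1 at 34 ± 18.9 CPM against 1002 ± 156 CPM (-4.88 ± 0.48, adjusted p = 1.74e-07), and Evx1 at -4.00 ± 0.29.

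General pluripotency, formative and cell cycle genes were higher at day 4. General pluripotency genes were higher for 7 of 10 and lower for 2 (adjusted p = 9.15e-05 and adjusted p = 0.114 with an estimated correlation). Pou5f1 (Oct4) was at 140.2 ± 41 CPM in the wild-type and 474 ± 14 CPM in the knock-out (1.76 ± 0.13, adjusted p = 2.76e-09), Utf1 at 3.27 ± 0.21, L1td1 at 1.57 ± 0.12 and Sall4, lower, at -0.92 ± 0.07. Formative genes were higher for 8 of 12 and lower for 3 (adjusted p = 0.00057 and adjusted p = 0.177 with an estimated correlation). Examples were Lin28b (0.79 ± 0.06), Zic5 (0.80 ± 0.06) and Sall2 (1.96 ± 0.15). The naive list did not pass, with 6 of 16 higher and 3 lower (adjusted p = 0.68; 7 higher and 3 lower adjusted over the list alone): Nanog was higher (1.16 ± 0.09) and Tbx3, which is also expressed in endoderm, lower (-7.29 ± 0.35). Proliferation genes were higher for 17 of 21 and lower for 1 (adjusted p = 2.87e-05 and adjusted p = 0.201 with an estimated correlation). Examples were Mcm5 (0.80 ± 0.05) and Ccne1 (1.00 ± 0.06). Genes of actins and SRF targets were higher for 10 of 19 and lower for 2 (11 higher and 2 lower adjusted over the list alone; adjusted p = 0.0489 and adjusted p = 0.691 with an estimated correlation). Examples were Srf (0.74 ± 0.07) and the calponin gene Cnn1 (2.22 ± 0.25). Imprinted genes were lower for 11 of 17 and higher for 2 (2 higher and 12 lower adjusted over the list alone; adjusted p = 7.11e-07). Peg3 was at 1500 ± 53.3 CPM in the wild-type and 170.4 ± 6.99 CPM in the knock-out (-3.14 ± 0.10, adjusted p = 9.08e-16), Usp29 at -3.27 ± 0.14 and Mest at -2.39 ± 0.12. Glycolysis and hypoxia genes were lower for 7 of 17 and higher for 1 (adjusted p = 0.027 and adjusted p = 0.686 with an estimated correlation). Examples were Slc2a3, from 2152 ± 359 to 174 ± 11.6 CPM, and Vegfa (-2.14 ± 0.11). Mesenchymal genes were lower for 6 of 9 and higher for 1 (1 higher and 7 lower adjusted over the list alone; adjusted p = 0.0293 and adjusted p = 0.62 with an estimated correlation). Examples were Cdh2 (-3.41 ± 0.28) and Zeb1 (-2.83 ± 0.34).

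The Wnt lists went both ways at day 4 and did not pass. Canonical targets were lower for 7 of 15 and higher for 3 (adjusted p = 0.198). The BMP pseudoreceptor Bambi was at -1.94 ± 0.13 and the Wnt antagonist Dkk1 at -4.30 ± 0.45. Ligands and receptors were lower for 10 of 28 and higher for 5 (adjusted p = 0.103). Fzd5 was at 495 ± 122 CPM in the wild-type and 39.6 ± 3.79 CPM in the knock-out and Fzd4, higher, at 1.72 ± 0.14. Intracellular components were higher for 5 of 20 and lower for 5 (adjusted p = 0.901). Examples were Tle4 (1.12 ± 0.07) and the transcription factor Tcf7l2 (-2.40 ± 0.20). Secreted inhibitors were higher for 2 of 7 and lower for 2 (3 higher and 2 lower adjusted over the list alone; adjusted p = 0.901). Examples were Sfrp2 (1.42 ± 0.13) and Sfrp1 (-4.12 ± 0.27). Of the other lists that did not pass, Nodal and Activin targets had 5 of 8 lower and 2 higher (adjusted p = 0.901; Gsc -2.37 ± 0.32, Smad7 1.11 ± 0.12). FGF and ERK feedback genes were 4 of 10 each way (4 higher and 5 lower adjusted over the list alone; adjusted p = 0.901; Dusp4 -1.60 ± 0.11, Etv5 1.28 ± 0.10). Neuroectoderm genes were 4 of 9 higher and 1 lower (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.162; Map2 1.69 ± 0.14, Nes 1.79 ± 0.17). For p53 targets 8 of 14 were higher and 2 lower (adjusted p = 0.269; Eda2r 0.86 ± 0.08, Perp -1.20 ± 0.13). Epithelial genes were 5 of 12 higher and 3 lower (adjusted p = 0.198; Cldn4 2.78 ± 0.25, Cdh1 0.44 ± 0.06). Methyltransferases of the SETD3 class with actin regulators had 7 of 14 higher and 1 lower (adjusted p = 0.288; Setd7 0.79 ± 0.10). Feeder genes were higher for 3 of 18 and lower for 1 (adjusted p = 0.25), with Thy1, also expressed outside fibroblasts, at 2.98 ± 0.34. Two-cell-like genes were lower for 2 of 10 (0 higher and 1 lower adjusted over the list alone; adjusted p = 0.901), Y-linked genes higher for 1 of 5 (adjusted p = 0.901), and the edgeR test called none of 18 Hox genes (2 at unadjusted p under 0.05, 0 by DESeq2).

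The strongest rises at day 4 were of the endocytic receptor Lrp2, from 10.1 ± 4.19 to 183 ± 15.4 CPM (4.17 ± 0.28, adjusted p = 1.03e-09), Ttbk1 (4.03 ± 0.25, adjusted p = 2.35e-12), Vat1l on chromosome 8 (3.76 ± 0.28, adjusted p = 5.1e-10), the auxilin gene Dnajc6 (3.70 ± 0.16, adjusted p = 5.08e-15) and the cytosolic DNA sensor Aim2 (3.65 ± 0.16, adjusted p = 2.57e-14). Besides Hnf4a, Hand1, Mesp1 and Kdr, the axon guidance receptor gene Robo3 was among the strongest falls, from 11.8 ± 3.23 CPM to 1 count, 778-fold with a counting interval of 133 to 29380. In all 9251 genes differed, 4511 higher and 4740 lower, 1281 and 1993 of them at least 2-fold. Of 29 lists 14 passed, 4 higher and 10 lower, 2 of them with an estimated correlation.

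**Figure D4:**
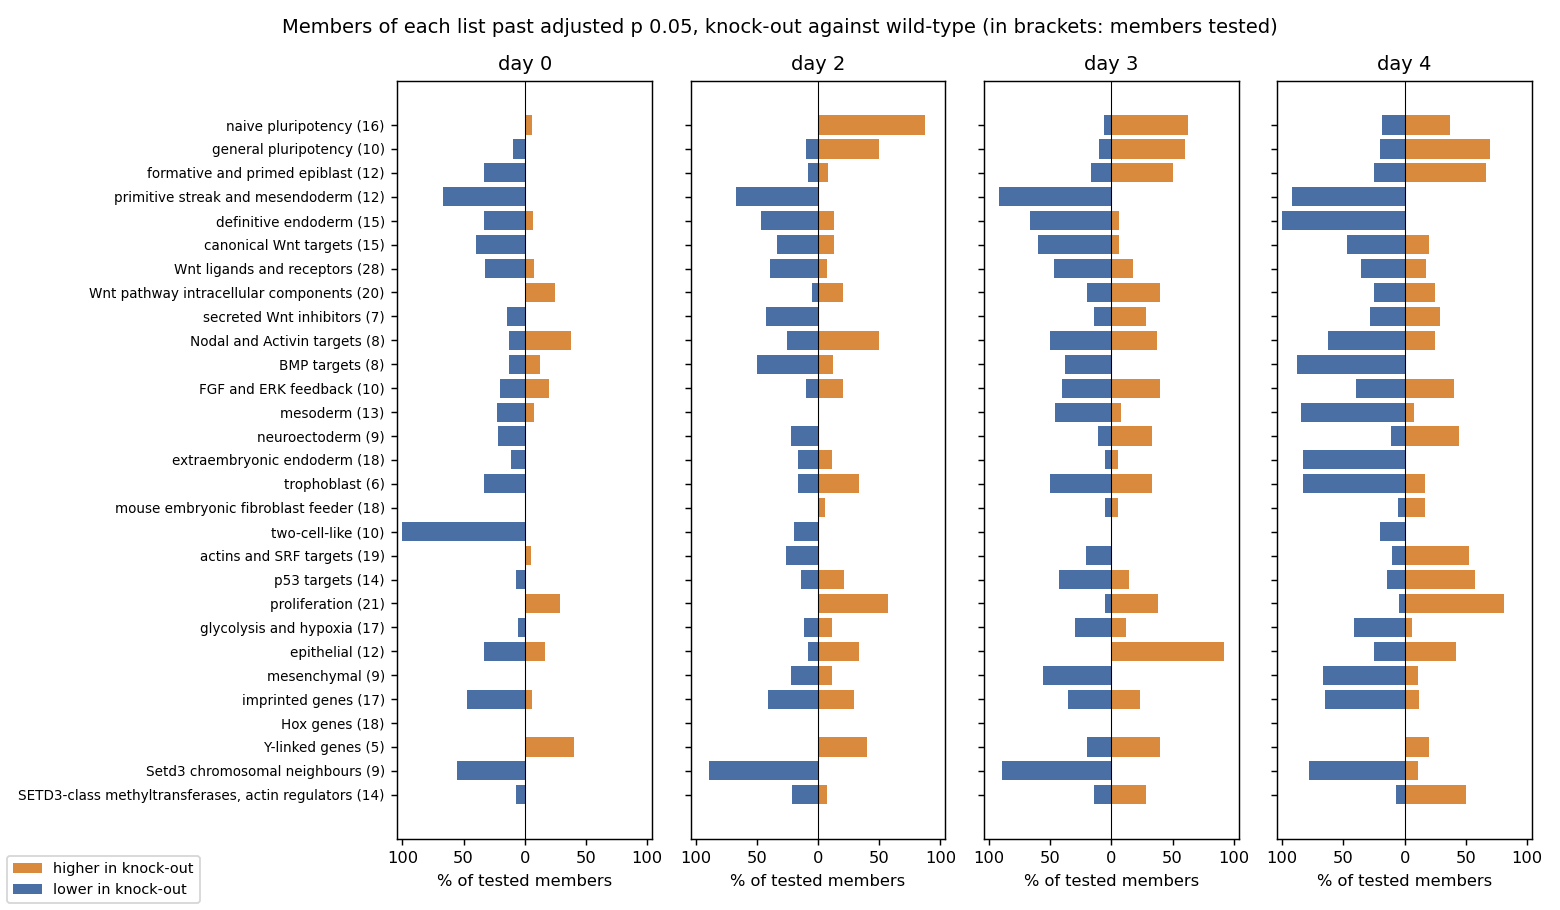
For each of 29 gene lists (vertical axis, with the number of tested members), the percentage of members past an adjusted p of 0.05 in the knock-out against wild-type comparison (horizontal axis), in 1 panel for each day; orange bars to the right are members higher in the knock-out and blue bars to the left members lower. Definitive endoderm goes from 5 of 15 lower at day 0 to 15 of 15 at day 4.

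The knock-out effect itself differed between days. Testing the effect at day 2 minus the effect at day 0, naive genes had a higher log2 fold change at day 2 for 12 of 16 and a lower one for none (14 higher and 0 lower adjusted over the list alone; adjusted p = 5.37e-24). Examples were Klf2 (difference in log2 fold change 1.78 ± 0.20, adjusted p = 1.91e-05), Esrrb (2.28 ± 0.28) and Zfp42 (1.62 ± 0.21). The median log2 fold change of the list went from 0.11 at day 0 to 1.44 at day 2. Formative genes had a higher value for 4 of 12 (5 higher and 0 lower adjusted over the list alone; adjusted p = 1.22e-08 and adjusted p = 0.0555 with an estimated correlation). Fgf5 was at 3.98 ± 0.16, adjusted p = 2.38e-14 and Dnmt3b at 0.80 ± 0.16. The median of this list was -0.22 at day 0 and -0.09 at day 2, nearer to 0. General pluripotency genes were higher for 4 of 10 (5 higher and 0 lower adjusted over the list alone; adjusted p = 0.00908 and adjusted p = 0.581 with an estimated correlation). Fgf4 was at 1.08 ± 0.25. Epithelial genes were higher for 3 of 12 (4 higher and 0 lower adjusted over the list alone; adjusted p = 0.00254 and adjusted p = 0.581 with an estimated correlation). Krt8 was at 2.65 ± 0.39 and Krt18 at 2.41 ± 0.39. Fgf5 was at 21.5 ± 3.11 CPM and 1.25 ± 0.229 CPM at day 0 and at 138 ± 10.3 CPM and 127 ± 6.08 CPM at day 2, wild-type first. Among Wnt targets Axin2 (1.40 ± 0.26) and Lgr5 (-3.37 ± 0.72) moved apart, and the list did not pass (adjusted p = 0.503). Setd3 differed by -0.26 ± 0.09, adjusted p = 0.0741. In all 1259 genes passed, 732 with a higher and 527 with a lower value at day 2, and 4 of 29 lists, 1 of them with an estimated correlation. Without replicate 1 of wild-type day 2, 731 genes passed.

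For the effect at day 3 minus the effect at day 0, formative genes were higher for 7 of 12 (adjusted p = 2.12e-13). Examples were Fgf5 (3.62 ± 0.16, adjusted p = 2.29e-13) and Sox3 (3.21 ± 0.33). Epithelial genes were higher for 9 of 12 (10 higher and 0 lower adjusted over the list alone; adjusted p = 4.34e-13). Examples were Grhl2 (1.42 ± 0.15) and Krt8 (3.51 ± 0.39). General pluripotency genes were higher for 5 of 10 and lower for 1 (5 higher and 2 lower adjusted over the list alone; adjusted p = 8.76e-07 and adjusted p = 0.102 with an estimated correlation). Dppa4 was at 2.66 ± 0.24 and Fgf4 at 3.07 ± 0.27. Naive genes were higher for 9 of 16 and lower for 1 (10 higher and 2 lower adjusted over the list alone; adjusted p = 0.000286 and adjusted p = 0.441 with an estimated correlation). Klf2 was at 2.02 ± 0.28. Canonical Wnt targets were lower for 5 of 15 and higher for 1 (2 higher and 6 lower adjusted over the list alone; adjusted p = 0.0175 and adjusted p = 0.441 with an estimated correlation). Lgr5 was at -5.01 ± 0.69, adjusted p = 3.79e-05 and Tnfrsf19 at -1.88 ± 0.30. Mesoderm genes were lower for 4 of 13 and higher for 1 (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.0471 and adjusted p = 0.441 with an estimated correlation). Snai1 was at -3.73 ± 0.36 and Pdgfra at -5.61 ± 0.77. Mesenchymal genes were lower for 4 of 9 (adjusted p = 0.0029 and adjusted p = 0.554 with an estimated correlation). Zeb2 was at -1.99 ± 0.33. Definitive endoderm genes were lower for 2 of 15 and higher for 1 (2 higher and 4 lower adjusted over the list alone; adjusted p = 0.0473 and adjusted p = 0.93 with an estimated correlation). Hhex was at -2.88 ± 0.57. Setd3 differed by -0.53 ± 0.09, adjusted p = 0.000116. In all 3282 genes passed, 1743 higher and 1539 lower, and 8 lists, 2 of them with an estimated correlation. With the effect at day 2 in place of day 0, 1877 genes passed, 1158 of them shared, the difference of Fgf5 turned to -0.37, and Krt8 (0.86), Lgr5 (-1.64), Zeb2 (-0.93), Klf2 (0.24) and Setd3 (-0.27) no longer passed.

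For the effect at day 4 minus the effect at day 0, endoderm and mesoderm genes were lower and formative and general pluripotency genes higher. Definitive endoderm genes were lower for 8 of 15 (adjusted p = 8.01e-08 and adjusted p = 0.127 with an estimated correlation). Shisa2 was at -3.31 ± 0.25, adjusted p = 3.96e-09, Prdm1 at -4.18 ± 0.30 and Sfrp5 at -8.01 ± 0.65. BMP targets were lower for 6 of 8 (1 higher and 7 lower adjusted over the list alone; adjusted p = 1.15e-05 and adjusted p = 0.127 with an estimated correlation). Smad6 was at -2.86 ± 0.23 and Msx2 at -6.00 ± 0.50. Mesoderm genes did so for 8 of 13 with 1 higher (adjusted p = 0.0015 and adjusted p = 0.127 with an estimated correlation). Tbx20 was at -5.32 ± 0.62 and Snai1 at -2.78 ± 0.34. Extraembryonic endoderm genes did so for 10 of 18 (0 higher and 11 lower adjusted over the list alone; adjusted p = 7.85e-05 and adjusted p = 0.13 with an estimated correlation). Pth1r was at -3.54 ± 0.46. Imprinted genes did so for 8 of 17 with 3 higher (3 higher and 9 lower adjusted over the list alone; adjusted p = 0.0015 and adjusted p = 0.127 with an estimated correlation). Peg3 was at -1.72 ± 0.13 and Mest at -1.76 ± 0.16. Mesenchymal genes did so for 5 of 9 (adjusted p = 0.00899 and adjusted p = 0.55 with an estimated correlation). Zeb1 was at -2.94 ± 0.39. Glycolysis and hypoxia genes did so for 5 of 17 with 2 higher (adjusted p = 0.0298 and adjusted p = 0.737 with an estimated correlation). Vegfa was at -2.23 ± 0.15. Formative genes were higher for 9 of 12 and lower for 2 (adjusted p = 2.25e-12). Fgf5 was at 3.86 ± 0.16 and Sox3 at 4.04 ± 0.33. General pluripotency genes did so for 7 of 10 with 1 lower (8 higher and 1 lower adjusted over the list alone; adjusted p = 4.47e-06 and adjusted p = 0.127 with an estimated correlation). Utf1 was at 3.12 ± 0.27 and Sall4 at -1.04 ± 0.10. Neuroectoderm genes did so for 4 of 9 with 1 lower (adjusted p = 0.0235 and adjusted p = 0.139 with an estimated correlation). Map2 was at 2.34 ± 0.20 and Nes at 2.69 ± 0.25. Epithelial genes did so for 7 of 12 (adjusted p = 0.00899 and adjusted p = 0.448 with an estimated correlation). Grhl2 was at 1.10 ± 0.15. Proliferation genes did so for 11 of 21 with 1 lower (adjusted p = 0.00899 and adjusted p = 0.55 with an estimated correlation). Ccne1 was at 0.99 ± 0.09 and Mcm5 at 0.55 ± 0.07. Actins and SRF targets did so for 9 of 19 with 1 lower (9 higher and 3 lower adjusted over the list alone; adjusted p = 0.0114 and adjusted p = 0.704 with an estimated correlation). Cnn1 was at 2.58 ± 0.34.

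The streak list did not pass in this test (adjusted p = 0.0677), with 3 of 12 higher and 2 lower (4 higher and 2 lower adjusted over the list alone). Neither did canonical Wnt targets (adjusted p = 0.776; 5 of 15 higher and 2 lower) or Wnt ligands and receptors (adjusted p = 0.982; 8 of 28 higher and 7 lower). T was higher (5.41 ± 0.82, adjusted p = 6.2e-05): at day 4 it was at 30.2 ± 12.3 CPM in the knock-out and 94.6 ± 29.1 CPM in the wild-type. The ligands Wnt3 (2.80 ± 0.31) and Fgf8 (4.19 ± 0.59), the transcription factor Lef1 (1.82 ± 0.22) and Fzd4 (1.84 ± 0.20) were higher as well, against Bambi (-1.71 ± 0.19) and Fzd5 (-3.74 ± 0.19). The strongest differences upwards, besides T, were of Clic5 (5.02 ± 0.42, adjusted p = 2.53e-09), Vat1l on chromosome 8 (4.87 ± 0.41, adjusted p = 1.59e-08) and Gbp2b, an interferon-inducible GTPase gene (4.63 ± 0.45, adjusted p = 2.15e-08). Downwards they were of Kdr (-8.21 ± 0.82, adjusted p = 1.82e-07), the pepsinogen gene Pga5, at 166 ± 74.2 CPM in the wild-type and 0.457 ± 0.0599 CPM in the knock-out at day 4 (-8.14 ± 0.82, adjusted p = 4.26e-07), Robo3, with 1 count in the knock-out of day 4, and Hnf4a, with 0. Setd3 differed by -0.65 ± 0.09, adjusted p = 2.6e-06. In all 6284 genes passed, 3072 higher and 3212 lower, and 13 lists, 6 higher and 7 lower, 1 of them with an estimated correlation. With the effect at day 2 in place of day 0, the difference of Fgf5 at day 4 was -0.13, and Pga5 (-4.34) and Grhl2 (0.29) no longer passed.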

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

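All tests of explanations in this part were chosen after the patterns were seen. The knock-out effect differed between days by a test of the difference itself for 1259 genes at day 2 against day 0, 3282 at day 3 and 6284 at day 4. Among named genes, the difference in log2 fold change for day 2 minus day 0 was Axin2 1.40, Dnmt3b 0.80, Esrrb 2.28, Fgf4 1.08, Fgf5 3.98, Klf2 1.78, Krt18 2.41, Krt8 2.65, Lgr5 -3.37 and Zfp42 1.62. For day 3 minus day 0 it was Dppa4 2.66, Fgf4 3.07, Fgf5 3.62, Grhl2 1.42, Hhex -2.88, Klf2 2.02, Krt8 3.51, Lgr5 -5.01, Pdgfra -5.61, Setd3 -0.53, Snai1 -3.73, Sox3 3.21, Tnfrsf19 -1.88 and Zeb2 -1.99. For day 4 minus day 0, 53 named genes were higher: Abcg1 1.07, Aim2 3.26, Axin2 0.95, Ccne1 0.99, Cldn4 2.59, Clic5 5.02, Cnn1 2.58, Dnajc6 3.03, Dnmt3b 1.50, Dnmt3l 2.25, Dppa2 2.26, Dppa4 2.82, Eda2r 0.75, Etv5 1.81, Fgf4 2.97, Fgf5 3.86, Fgf8 4.19, Fzd10 0.96, Fzd4 1.84, Gbp2b 4.63, Grhl2 1.10, Krt18 1.28, Krt8 1.42, L1td1 1.38, Lef1 1.82, Lin28b 0.74, Lrp2 3.88, Map2 2.34, Mcm2 0.43, Mcm5 0.55, Nanog 1.29, Nes 2.69, Plk1 0.18, Pou3f1 4.00, Pou5f1 1.82, Sall2 2.41, Setd7 1.20, Sfrp2 2.02, Slc35d3 3.78, Smad7 0.78, Sox3 4.04, Srf 0.63, T 5.41, Thy1 2.83, Tle4 0.78, Tnfrsf19 1.31, Ttbk1 3.27, Ttc7b 0.51, Utf1 3.12, Vat1l 4.87, Wnt3 2.80, Wnt8a 4.56 and Zic5 0.83. The 36 that were lower were Ascl2 -3.10, Bambi -1.71, Cdh2 -2.66, Dusp4 -1.48, Eml1 -2.75, Evx1 -1.54, Fzd5 -3.74, Gata4 -5.62, Id1 -4.41, Kdr -8.21, Krt7 -1.73, Lgr5 -2.98, Lrp6 -0.21, Mest -1.76, Msx2 -6.00, Pdgfra -4.30, Peg3 -1.72, Perp -0.86, Pga5 -8.14, Prdm1 -4.18, Pth1r -3.54, Sall4 -1.04, Setd3 -0.65, Sfrp1 -4.42, Sfrp5 -8.01, Shisa2 -3.31, Slc2a3 -3.52, Smad6 -2.86, Snai1 -2.78, Tbx20 -5.32, Tbx3 -7.49, Tcf7l2 -2.49, Trh -1.71, Usp29 -1.22, Vegfa -2.23 and Zeb1 -2.94. These have over 3 counts in each group. Hand1, Hnf4a and Robo3, with at most 1 count in the knock-out of day 4, and Tal1 and Uba1y, with 3 and 2 counts in the wild-type of day 4, passed as well.

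The 3 libraries against 3 of a comparison make 10 splits, too few for a share under 0.05. With the compared groups alone, the real split had the largest number of genes in each (1 of 10): 1587, 6352, 7229 and 8777 genes for knock-out against wild-type at days 0, 2, 3 and 4, and 10235, 6520 and 6799 for the wild-type steps, with 0 as the highest of the other splits. For gene lists the real values were 11, 14, 11 and 15 at the 4 days and 12, 14 and 14 in the wild-type steps, with 20, 9, 10, 11, 11, 9 and 14 as the highest others, so that 5 of 10 splits were as large at day 0 and 2 of 10 in the step to day 4. For the genotype effect between days, 100 splits were drawn. For genes, 5, 5 and 3 of 100 were as large at days 2, 3 and 4 minus day 0 (980, 2511 and 5259 genes, highest others 5912, 6416 and 7708). For lists it was 91, 51 and 17 of 100 (5, 8 and 13 lists, highest others 20, 19 and 17), so that chance could not be excluded there. The shares for genes do not settle chance at any of these days. The other splits with a count as large as the real one point to a structure of the samples: all of them (4, 4 and 2) left the genotypes of the later day unmixed. The 75 splits that mixed both days put the genotype difference inside each group and had at most 0, 1 and 0 genes.

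On chromosome 12 of the knock-out, 1 block was raised and the distal block around Setd3 lowered. A trend with GC content or length was argued against, since the corrected medians stayed at 1.10 or more for the raised block and at -0.80 or less for the lowered one. Regulation of the imprinted cluster alone was argued against by a median of -0.74 or less without its imprinted genes. A change in the number of copies of these blocks in the knock-out line is a candidate explanation. It was tested on genes under 5 CPM, which had not set the ends of the blocks: medians were 0.58 or more for 33 genes of the raised block (95% interval 0.00 to 0.92 at day 3) and -0.81 or less for 36 genes of the lowered block (-0.98 to -0.59 at day 0). With 1 knock-out line, it is open which genotype differences follow from Setd3 and which from these blocks; RNA alone does not measure copies.

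Chromosome 8 was slightly raised, with medians between 0.19 and 0.30 in 4 parts of its length. GC content or length was argued against by corrected medians of 0.21 or more, above the uncorrected medians of the other autosomes and X (at most 0.10). An additional copy in part of the knock-out cells stays open. The 271 genes under 5 CPM had medians of -0.03, -0.073, 0.12 and -0.05 (95% interval at day 2 -0.20 to 0.03, computed after the medians were seen), above such genes on each other autosome but 12 and on X at days 0, 2 and 3 but not at day 4; the bound of 0 set for this test did not allow for medians below 0 on those chromosomes (down to -0.40). No biological explanation was tested.

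Setd3 transcripts remained in the knock-out. Unedited cells mixed into these cultures were argued against by 15 genes at day 0 with at least 10 CPM in the wild-type whose remaining share was more than 4 times smaller than that of Setd3; at days 2, 3 and 4 there were 4, 37 and 87. RNA of feeder cells was argued against, since the feeder sum in the knock-out fell to 8.02% of its day 0 value or less while Setd3 stayed at 64.7% or more. Loss of 1 copy of the lowered block alone was argued against, since Setd3 lay below the block's median by a log2 difference of -0.67 or more in size, and 2, 2, 1 and 5 of the 61 genes lay as low at days 0, 2, 3 and 4. A transcript that carries the edit may remain, which these counts do not resolve.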

How the results depend on the processing

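The effect at day 2 in place of day 0 and leaving out chromosome 8 and distal chromosome 12 were chosen after the data were seen; the other alternatives before the data were examined. All 354 results of named genes kept direction and side of the threshold under DESeq2's size factors, DESeq2's Wald test, only the groups compared and the replicate block, 353 with no filter, and 309 of 309 without chromosome 8 and distal chromosome 12. With 1 library left out, 2487 of 2496 did: Rfx3 at day 2 no longer passed in 4, Axin2 at day 2 reversed (-0.03 without replicate 2 and -0.10 without replicate 3 of wild-type day 2, -0.05 without replicate 2 of knock-out day 2; highest 0.19 without replicate 1 of wild-type day 2), and Setd3 at day 2 minus day 0 passed in 2 (-0.32 and -0.31). With the effect at day 2 in place of day 0, 42 of 51 were the same; Fgf5 reversed at day 3 (-0.37) and day 4 (-0.13), and Krt8 (0.86), Lgr5 (-1.64), Zeb2 (-0.93), Klf2 (0.24) and Setd3 (-0.27) at day 3 and Pga5 (-4.34) and Grhl2 (0.29) at day 4 no longer passed.

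Of the counts of genes and lists 265 stayed within 1.5 times and 15 moved. With only the groups compared, 1587 genes passed at day 0 (1539 shared) and 6352, 7229 and 8777 at days 2, 3 and 4. With an estimated correlation, 4, 2, 2 and 2 lists passed at days 0, 2, 3 and 4, 2 in each wild-type step, and 1, 2 and 1 for the differences between days. The effect at day 2 in place of day 0 gave 1877 genes at day 3 (1158 shared). Leaving out 1 library gave 2649 to 3594, 4157 to 4740.0, 5676 to 6666 and 8354 to 8939 genes at days 0, 2, 3 and 4, 10335 to 10568, 6021 to 6668 and 6773 to 7480 in the wild-type steps, and 731 to 1645, 2533 to 3611 and 5611 to 6370 for the differences; for lists 10 to 15, 8 to 10, 10 to 12 and 12 to 15, then 10 to 11, 11 to 14 and 12 to 14, then 4 to 7, 5 to 8 and 11 to 16. Without replicate 1 of wild-type day 2, 731 genes passed at day 2 minus day 0 (715 shared); without replicate 3 of knock-out day 0, 7 lists passed there, and without replicate 1 of wild-type day 0, 5 lists at day 3 minus day 0. The cause was not tested.

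Replicate numbers are shared by all groups. They were not taken as pairs, because same-numbered libraries deviated together by a correlation of 0.017 on average (-0.15 to 0.165 over 84 pairs). As a hint from the data, 19 of 24 libraries were closest to their own number, against 7.9 on average in 1000 permutations of the numbers within groups, of which 1 reached 19. With the replicate block, 3663, 5525, 7132 and 9326 genes passed at days 0, 2, 3 and 4, and 10, 10, 10 and 13 lists, then 10, 13 and 13 in the wild-type steps and 4, 7 and 13 for the differences; at day 4, in the step to day 4 and at day 3 minus day 0, 1 list fewer passed than without it. DESeq2's size factors moved the median log2 fold change by under 0.05, and the Y-linked list at day 2 went from an adjusted p of 0.0495 to 0.0503.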

Other observations

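Genes of primary cilia were lower in the knock-out at days 2, 3 and 4. This list of 39 genes was made after 3 of them, Bbs1 and Ttc26 included, had been seen, and holds no gene of chromosome 8 or distal chromosome 12. In edgeR's test 8 were lower and 0 higher at day 0, 27 and 0 at day 2, 29 and 1 at day 3 and 31 and 2 at day 4. Under 12 alternatives 5 to 9 were lower at day 0, with 5 when only the groups compared were fitted and 5, with 1 higher, without replicate 2 of knock-out day 0. At days 2, 3 and 4 it was 23 to 30, 27 to 30 and 27 to 31. Without the 3 genes seen first, 5, 24, 26 and 28 of 36 were lower, with median log2 fold changes of -0.16, -0.38, -0.47 and -0.55 (camera with an estimated correlation p = 0.0912, 0.00137, 0.00338 and 0.00756). At day 4 the transport gene Ttc26 was at 38 ± 2.9 CPM in the wild-type and 9.36 ± 0.735 CPM in the knock-out (-2.02 ± 0.10, adjusted p = 5.85e-14) and the kinesin genes Kif3a and Kif3b at -1.43 ± 0.09 and -0.98 ± 0.06; Traf3ip1 (0.71 ± 0.08) and Ttc21b (0.80 ± 0.08) were higher. The ciliary transcription factor Foxj1 was lower at day 2 (-1.61 ± 0.36, adjusted p = 0.00249), day 3 (-2.64 ± 0.35, adjusted p = 1.07e-05) and day 4 (-2.53 ± 0.32, adjusted p = 2.93e-06), as was Rfx3 at days 3 and 4 (-0.79 ± 0.12 and -0.63 ± 0.12). At day 2 Rfx3 was at -0.35 ± 0.12, adjusted p = 0.0304, a call lost with no filter (-0.34), without replicate 1 (-0.25) or 3 (-0.37) of the wild-type and without replicate 1 (-0.32) or 2 (-0.31) of the knock-out. Rfx2 was higher at day 2 (0.79 ± 0.14) and lower at day 4 (-1.14 ± 0.17).

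The tests in this paragraph were chosen after the result was seen. By distance over genes with a mean of at least 5 CPM, the knock-out lay nearest to wild-type day 0 at day 0, to day 2 at days 2 and 3, and to day 3 at day 4 (distance 48.6). A delay may account for part of this. Knock-out day 4 lay a median of 43.2% (quartiles 12.34 to 89.61) of the way from wild-type day 2 to 3 over 337 rising genes. Over 502 falling genes it was 79.47% (39.2 to 102.8). For 10 genes the libraries of knock-out days 2, 3 and 4 all lay on the same side of all wild-type libraries. Their means were at least 2-fold beyond every wild-type group mean (for 6, 2-fold beyond every wild-type library). The 100 simulations (0 such genes) held no genotype difference but a delay, so whether other genes were delayed stays open. The 10 genes included Xlr3a (-6.68 at day 4), Nxf3 (-3.89), Penk (-3.49), Dusp18 (-2.63), Ttc26, Bbs1 (-1.98) and Spata6 (-1.96) among the 8 on the lower side, and 2810429I04Rik (1.54) and Gm9575 (1.51) on the higher. Of the 10, Xlr3a, Nxf3 and Gm9575 lay outside at day 0 too.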
